A study of Plasmodium falciparum with 4 samples.

How the data were processed

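The samples were 4 two-colour oligonucleotide arrays of one group. Per the labels' protocols, parasites of strain K1 were freed from red cells with saponin and total RNA was extracted with Trizol. For purification, 100 µg of total RNA was incubated for 10 min with bead-bound GST-PfeIF4E and eluted with detergent. For labelling, 20 µg of total RNA and 2 µg of purified RNA were primed with an oligo-dT of 21 nucleotides, and the cDNA was coupled to Cy5 and Cy3 respectively. Hybridization solutions held 1 pmol/µl of Cy5 and 0.25 pmol/µl of Cy3. Because priming was from oligo-dT in both channels, a transcript with a short or no poly(A) tail was measured in either channel only as far as it was primed.

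The values used were the log2 ratios of red over green per oligo and array deposited by the authors. Per the file headers they are log2(R/G), with array medians near 0; the image analysis, background correction, spot filter and normalization are not given in the sources used here. Of 20380 values, 2377 were blank in the deposited log2 ratios and were filled in a second deposited sheet, per the SAM settings from 10 nearest neighbours. The authors' deposited table also gave a mean log2 ratio, a fold change (a linear ratio, equal to 2 to the power of that mean) and the score and q-value of a one-class SAM test. Per the file headers that test used 100 permutations, a delta of 0.59, an s0 of 0.442 and a pi0 of 0.706, with arrays not centred. The file did not say which channel was red; red was taken as Cy5, so the sign was turned to give purified over total RNA. Array numbers are those of the deposited columns, and no label ties them to samples or purifications. Channel intensities were not used here, so no value could be set against signal strength.

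Gene identifiers and descriptions were those of the deposited table, an older PlasmoDB annotation. None of 3890 identifiers (0) matched the RefSeq gene table provided, which names genes by another system, so no coordinates, coding lengths or GC contents are given, and the planned check of ratio against abundance, length and GC was void. Of the oligos, 149 had no identifier and were kept under their oligo name, and 742 genes had more than 1 oligo. Oligos of one gene were averaged on each array, control and empty spots were left out, each array was centred on its median gene, and genes with a value on at least 3 of 4 arrays were tested.

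The test was a one-sample moderated test against 0 (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 3582 genes and a threshold of 0.05. Standard errors are those of the moderated fit. Gene lists were case-insensitive patterns on identifier and description, tested with cameraPR on the moderated statistics with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20 fixed lists with at least 5 genes and, separately, over 4 lists added after the data were seen. The same test was run beside it with each list's correlation, estimated from its genes with values on all 4 arrays. Run on those genes too was fry, which tests a list against no change and not against other genes. Agreement between arrays was given as Pearson and Spearman correlations across genes without a test.

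Genes were named by a rule set before the data were examined: up to 10 highest and 10 lowest genes past the threshold with values of one sign on all 4 arrays, the eIF4E bait, for each list with a call the 2 members past the threshold with the largest shift, members of lists with under 5 measured genes, and the 3 top and 3 bottom genes of the authors' deposited table. The rule gave 25 genes, of which 15 passed the threshold; one gene is not reported here by name or in the figures, but counts and gene lists include it.

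On simulated data with 200 of 3582 genes shifted and the other genes at 0, over 20 simulations, the gene test recovered 65.4% of genes shifted by a log2 ratio of 1, 93.3% of those shifted by 2 and 97.9% of those shifted by 3, and on average 4.0% of its calls were false. Lists of 30 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 100% of simulations, and unshifted lists in 0.2%. These simulations drew arrays as independent, without the unequal correlation seen between the real arrays. Genes were drawn as independent too, while some real lists had estimated correlations above 0, such as 0.057 (cytosolic ribosomal proteins) and 0.235 (plastid genes). The share of 0.2% therefore does not cover lists of correlated genes.

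Alternatives set before the data were examined were no further centring, centring on the mean, the imputed values, other minimum numbers of arrays, each oligo on its own, robust eBayes, leaving out each array, a threshold of 0.1, a test against an absolute log2 ratio of 0.5, the authors' SAM calls and SAM recomputed over all 16 sign flips. In the recomputed SAM the false calls were first averaged over flips, which could not give a q-value under 5% because the flips include the data and their mirror image; the median over flips was then used. Alternatives chosen after the data were seen were averages of arrays in pairs, removal of print block, row and column medians, leaving out a series of numbered oligos, and the added lists. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.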

Results

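The series compared 2 RNA populations of the malaria parasite Plasmodium falciparum, strain K1, grown in asynchronous blood-stage culture. One was total RNA. The other was the RNA held back from it by beads carrying GST-PfeIF4E, the parasite's own eIF4E fused to glutathione S-transferase; eIF4E is the translation initiation factor that binds the methylated guanosine cap at the 5′ end of an mRNA. The question named by the series was the cap status of parasite mRNAs, and the comparison asked which transcripts were recovered more or less by the cap-binding protein than the median transcript. All 4 arrays carried the same comparison, with total RNA in Cy5 and purified RNA in Cy3, and came from 2 independent purifications of separate cultures. No label tied an array to a purification, so the p-values below rest partly on technical spread and are too small. The dyes were not swapped, so an effect of the dye on a single oligo could not be separated from the effect of purification.

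The deposited values covered 5095 spots per array, of which 16 were control or empty spots. Each of these spots had a value on at least 2 arrays, and one control spot was numbered 6910. Spots with fewer values were absent from the deposited values, so the blank shares below describe only the spots kept. Values were kept for most of the other 5079 oligos on arrays 1 and 2, where 2.6% and 3.5% were blank, and for fewer on arrays 3 and 4, where 18.3% and 21.9% were blank. Ratios are given as log2 of purified over total RNA with each array's median gene at 0, taking red as Cy5, so a negative value means that a transcript was recovered less than the median transcript and not that it was absent from the purified RNA. Most genes lay near 0: of 3582 genes with a value on at least 3 arrays, 83.6% had a mean within 0.5 of 0. The number of arrays limits the precision of every value.

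Transcripts encoded in the parasite's organelles were among those with the lowest ratios. The mitochondrial coxI transcript, which encodes a core subunit of cytochrome c oxidase, had the lowest ratio of all genes tested, at -3.73 ± 0.36 (SE, n = 4), or 13.3-fold lower in purified than in total RNA (limma adjusted p = 0.0103). It was lower on 4 of 4 arrays, with values from -5.02 to -2.68. Several transcripts of the plastid genome (the apicoplast, a non-photosynthetic organelle with its own small genome) were also low. Genes not labelled as organelle-encoded, such as PF11_0489 at -2.49, lay among them. The plastid tRNA-Thr was at -2.79 ± 0.42 (SE, n = 4, adjusted p = 0.0354) and tRNA-Pro at -1.48 ± 0.24 (SE, n = 4, adjusted p = 0.0392). Among plastid genes for ribosomal proteins, rpl2 was at -1.92 (adjusted p = 0.0354), rpl36 at -1.79 (adjusted p = 0.0219) and rps12 at -1.48 (adjusted p = 0.0149). The plastid gene tufA, which encodes the organelle's translation elongation factor Tu, was at -1.51 ± 0.17 (SE, n = 4, adjusted p = 0.0149). Each of these 7 transcripts was lower on 4 of 4 arrays, which the rule for naming the lowest genes required.

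Of the 27 plastid genes tested, 7 were lower and none was higher past the threshold over all genes, while 16 were lower and 4 higher when adjusted over the list alone. The count depended on single arrays: it was 0 without array 2, 12 lower and 2 higher without array 3, 11 lower without array 4 and 9 lower and 1 higher without array 1. Their median was -1.17 (-1.14 without array 2), with medians of -1.80, -1.42, -0.78 and -0.53 on arrays 1 to 4. As a group they lay below other genes (camera adjusted p = 7.32e-07), at adjusted p = 0.0551 with an estimated correlation. After adjustment for position on the slide, 6 of the 27 were lower and 1 higher, with a smaller median shift of -0.93 (camera adjusted p = 0.00012 with the preset correlation). The 16 plastid protein genes had a median of -1.06 (adjusted p = 5.58e-05, and adjusted p = 0.0308 with an estimated correlation). The 11 plastid tRNA and rRNA genes had a median of -1.17 (adjusted p = 0.000524, and adjusted p = 0.247 with an estimated correlation). These plastid lists were drawn up after the data were seen, since the pattern fixed beforehand for the plastid genome matched tufA alone and that for the mitochondrial genome matched no gene. A list fixed beforehand for structural RNA, which held 10 genes and was nearly all plastid tRNA, had a median of -1.17 and 2 genes lower, or 6 when adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.403 with an estimated correlation). Its call was lost without array 3, at adjusted p = 0.0719 with a median of -1.18, and after adjustment for position on the slide, at adjusted p = 0.0685 with a median of -0.92.

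The depletion did not extend to every plastid oligo. Of 35 plastid oligos, 26 had a mean below 0, 22 of them on each array measured, and 9 had a mean above 0. When every oligo on at least 2 arrays was tested on its own, 11 plastid oligos were lower past the threshold and 1 was higher, that for the open reading frame ORF129 (mean 2.14, above 0 on the 3 arrays that measured it, adjusted p = 0.0494). Both tufA oligos were low, at -1.50 over 4 arrays and -1.47 over 3. The 2 spots named for the plastid Clp protease disagreed: one was at -3.28 over 4 arrays and the other at 0.66 over 2 arrays, and their average as a gene did not pass the threshold (-2.27, adjusted p = 0.0605). The 16 control and empty spots had means between -0.53 and 0.67, with a median of 0.12.

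**Figure D1:**
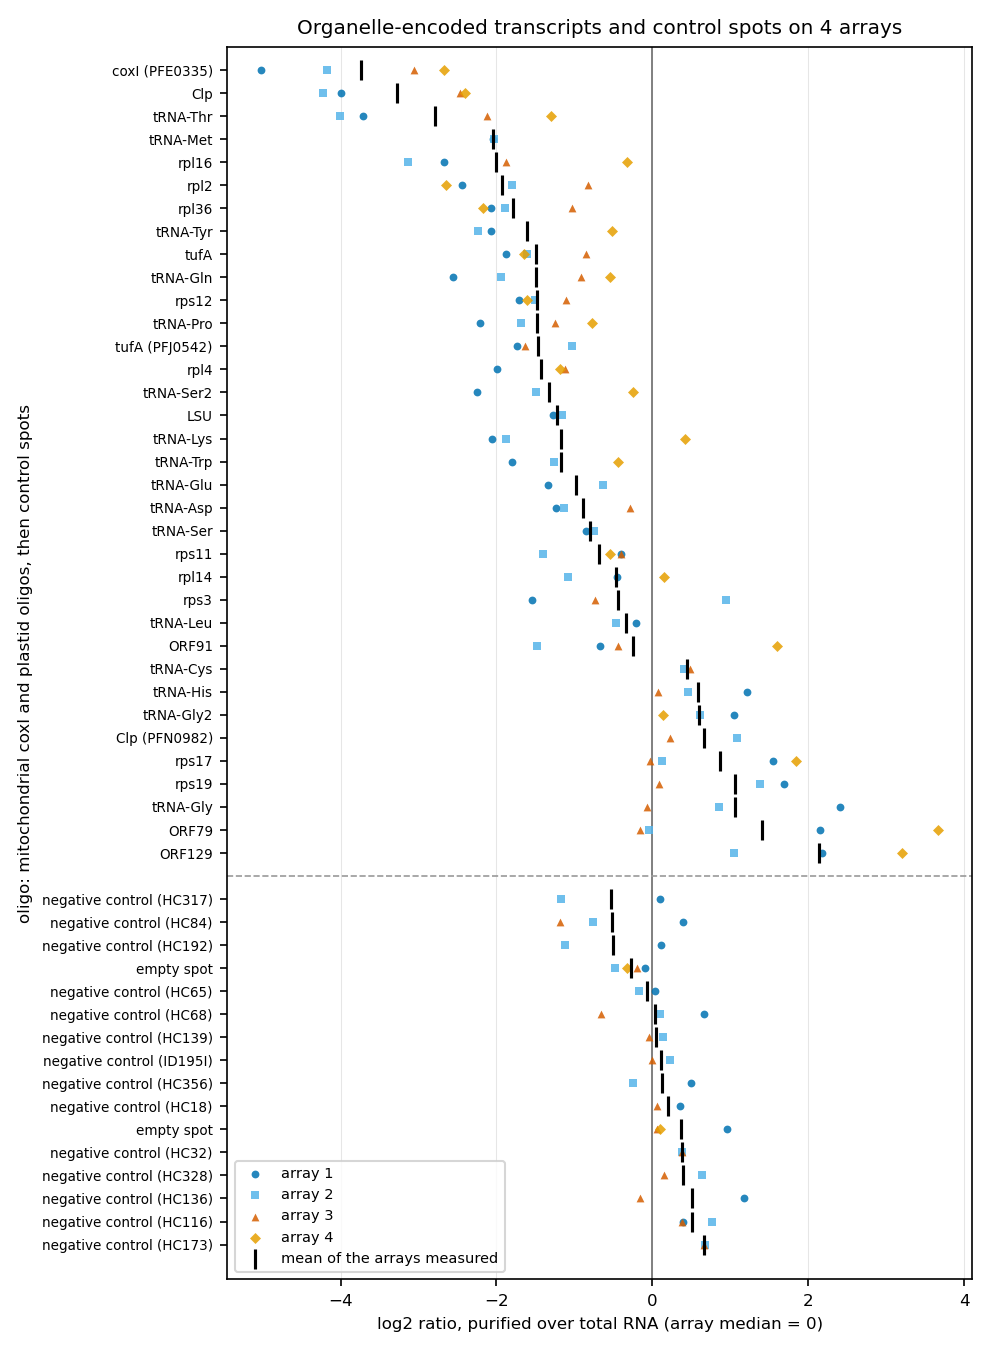
Log2 ratio of purified over total RNA (horizontal axis) for the mitochondrial coxI oligo, 34 plastid oligos and, under the dashed line, 16 control and empty spots (vertical axis), with one point per array and a bar at the mean of the arrays measured. Of the plastid oligos drawn, 25 have a mean below 0 and 9 above 0, and the means of control and empty spots lie between -0.53 and 0.67.

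Across all 3582 genes, 8 were higher and 25 lower in purified RNA at an adjusted p under 0.05 in a one-sample limma test. Each of the 33 had one sign on all arrays that measured it, but passing on so few values favours this, so it is not separate support. Of the 25 lower genes, 8 were organelle transcripts and 17 were others. The lowest of these others with a value on all 4 arrays were PF11_0489, a hypothetical protein, at -2.49 ± 0.23 (SE, n = 4, adjusted p = 0.0103), and MAL8P1.40, a putative RNA-binding protein, at -1.40 ± 0.20 (SE, n = 4, adjusted p = 0.0311). Higher genes with a value on all 4 arrays were fewer, and none was shifted as far as coxI or PF11_0489. PF10_0268, merozoite capping protein-1, was at 1.5 ± 0.25 (SE, n = 4, adjusted p = 0.045), or 2.82-fold higher in purified RNA. PFE0350c and PF13_0049, which encode the ribosomal proteins L4/L1 and L24 of the large cytosolic subunit, were at 1.38 ± 0.24 and 1.31 ± 0.20 (SE, n = 4 each, adjusted p = 0.0459 and 0.0354). PFA0620c, the glutamic acid-rich protein GARP, was at 1.09 ± 0.17 and PF10_0345, merozoite surface protein-3, at 1.05 ± 0.18 (SE, n = 4 each, adjusted p = 0.0383 and 0.0448). All 5 were higher on 4 of 4 arrays, which the rule that named them required.

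The count of genes depended on single arrays. Without array 2 no gene passed in the limma test (129 higher and 174 lower at an unadjusted p under 0.05), and without array 3 there were 104 higher and 60 lower; with the 4 arrays averaged into 2 pairs, no gene passed when arrays 1 and 2 and arrays 3 and 4 were averaged, 494 when 1 and 3 and 2 and 4 were, and 4 when 1 and 4 and 2 and 3 were. If arrays 1 and 2 came from one purification and arrays 3 and 4 from the other, no gene would therefore pass. In that case coxI would stay at -3.73 and the plastid genes would have a median of -0.99 (camera adjusted p = 3.51e-06 with the preset correlation of 0.01). That camera test takes genes as its units, so its p-value does not measure the spread between purifications. An estimated correlation was not run for this pairing, and over the 4 single arrays it gave a camera adjusted p of 0.0551. The authors' deposited table, from a one-class SAM test, listed 193 oligos higher in purified RNA and 178 higher in total RNA at a q-value of up to 5%. All 41 oligos with a q-value of 0 in the authors' deposited table were higher in total RNA, led by coxI, a Clp spot and PF11_0489. At its other end stood oligos for PF11_0111, an asparagine-rich antigen, PF13_0049 and PF10_0268, with a q-value of 0.736%; the average of all 3 PF11_0111 oligos did not pass in the limma test (0.45, adjusted p = 0.187).

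**Figure D2:**
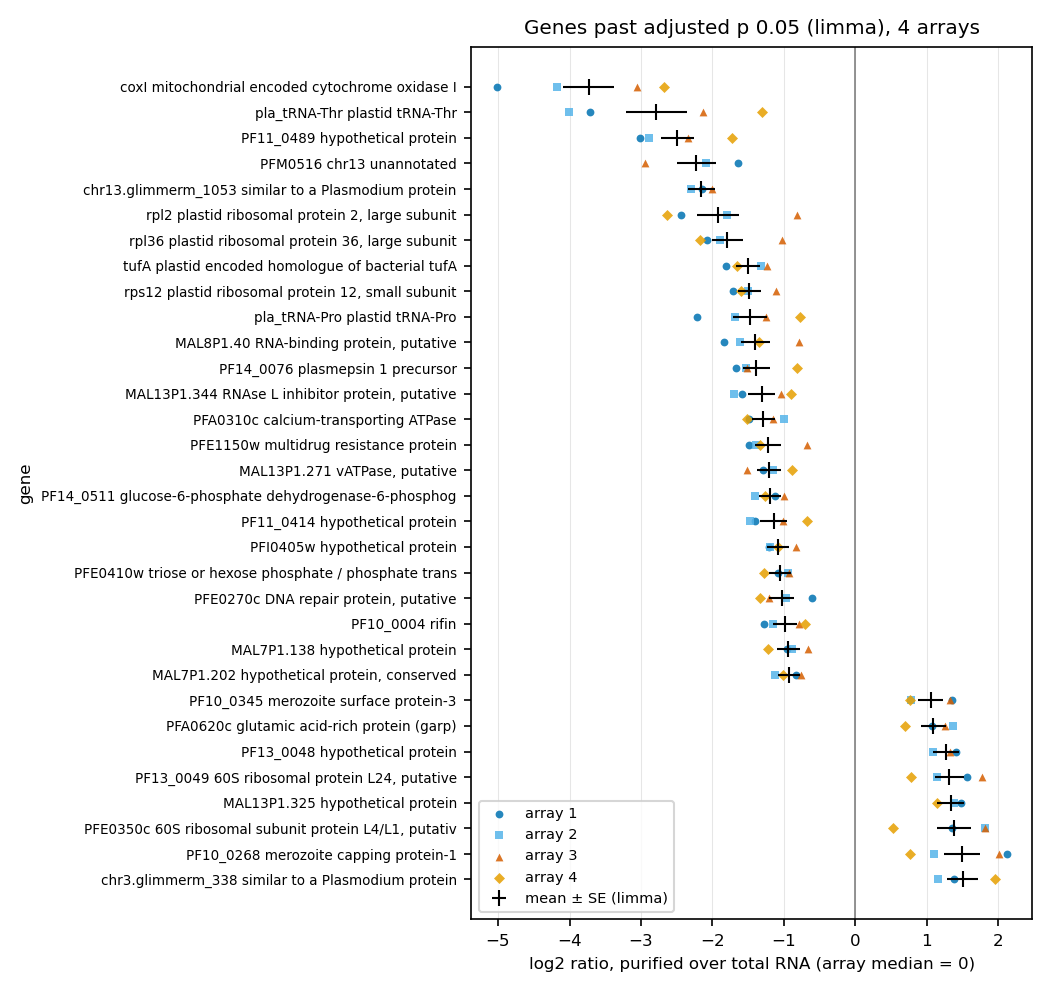
Log2 ratio of purified over total RNA (horizontal axis) for 32 of the 33 genes past an adjusted p of 0.05 (vertical axis), with one point per array and the mean ± SE of the limma fit in black. The 24 lower genes drawn run from coxI at -3.73 to -0.93, and the 8 higher genes lie between 1.05 and 1.5.

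The eIF4E transcript itself was examined apart, because the bait protein was made from its coding sequence. PFC0635c, annotated as a putative translation initiation factor E4, was not enriched in purified RNA: its ratio was -0.44 ± 0.20 (SE, n = 4) and did not pass the threshold (limma adjusted p = 0.286). It was below 0 on 3 of 4 arrays, with values of -0.455, 0.059, -1.07 and -0.31 on arrays 1 to 4, and its mean was -0.24 without array 3 and -0.61 without array 2.

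Among the gene groups fixed before the data were examined, transcripts of cytosolic ribosomal proteins were recovered slightly more than other transcripts. Of 72 such genes, 53 lay above 0, with a median of 0.18 and medians of 0.15, 0.09, 0.37 and 0.24 on arrays 1 to 4. As a group they passed the camera test over 20 lists (adjusted p = 0.00429), at adjusted p = 0.205 with an estimated correlation. Single members past the threshold were PFE0350c and PF13_0049, also 2 when adjusted over the list alone, and none was lower. The call was lost without array 3, at adjusted p = 0.0837 with a median of 0.15.

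Genes of merozoite surface and invasion proteins, which act when the parasite enters a red cell, had a median of 0.20 over 24 genes, of which 18 lay above 0. PF10_0268 and PF10_0345 were the 2 that passed, 3 when adjusted over the list alone (with PF07_0128, an erythrocyte binding antigen, at 0.79, chosen after its value was seen), but the group did not (adjusted p = 0.0941); its median was 0.12 without array 2 and 0.05 over genes on all 4 arrays. Genes for the digestion of haemoglobin had a median of -0.21 over 15 genes (-0.33 with each oligo on its own and -0.34 without a set of numbered oligos). One of them passed as lower, PF14_0076, which encodes plasmepsin 1, an aspartic protease of the food vacuole, at -1.38 (adjusted p = 0.0297; chosen after its value was seen), and the group did not pass (adjusted p = 0.132). The 26 genes of splicing and RNA processing had a median of 0.12 (adjusted p = 0.122; 0.07 without array 1 and 0.19 without array 4) and the 10 genes of tubulin and actin a median of -0.19 (adjusted p = 0.196; -0.30 without array 3 and -0.12 without array 4). The list for organellar ribosomal proteins took in plastid-encoded genes beside nuclear ones. It had a median of -0.10 over 24 genes and 4 genes lower, all plastid-encoded, or 7 lower and 2 higher when adjusted over the list alone (adjusted p = 0.196). Without the plastid-encoded genes, 13 genes had a median of 0.21 and none passed (adjusted p = 0.115). The contrast between plastid-encoded and nuclear-encoded members was not tested.

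No shift passed for translation factors (32 genes, median -0.05, adjusted p = 0.472), tRNA ligases (31, -0.03, 0.837), proteasome subunits (26, -0.08, 0.452), chaperones (44, -0.07, 0.726) or histones (5, -0.05, 0.595). Glycolytic enzymes (12 genes) had a median of 0.05 and a mean of -0.01 (adjusted p = 0.951). DNA replication (31 genes, median -0.01, adjusted p = 0.951), protein kinases (52, -0.03, 0.698), mRNA capping and decay (6, -0.12, 0.587) and early transcribed and exported proteins (12, -0.13, 0.452) did not pass either. When adjusted over their list alone, 1 gene each passed among splicing genes (PF10_0217, at 0.96), tubulin and actin genes (PF14_0218, at -0.84), histones (PF13_0185, at -0.72) and the protein kinase list (PF11_0257, at -1.38), all 4 named after their values were seen. PF11_0257 is described as an ethanolamine kinase, not a protein kinase, and entered that list through its pattern on descriptions. The multigene families, whose oligos can hybridise to several members, were measured with few oligos: PfEMP1 genes had a median of 0.17 (8 genes, adjusted p = 0.457) and rifin and stevor genes one of -0.07 (9 genes, adjusted p = 0.587), with 1 rifin, PF10_0004, lower at -0.98 (adjusted p = 0.0459; chosen after its value was seen, and uncertain for the same reason). A list meant for RNA of human blood cells matched 9 parasite genes described by their similarity to human proteins (median 0.09, adjusted p = 0.951) and measured no host RNA. Serine-repeat antigens were matched by no gene description.

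Markers of other parasite stages were too few for a group test. Of 4 sexual-stage genes, PF13_0011, gamete antigen 27/25, had a ratio of -0.84 (adjusted p = 0.11), PFD0310w of -0.41, PF13_0258 of -0.015 and PFL2405c, PFG377, of 0.60 (n = 3; 0.075 without array 1), and none passed over all genes. Single arrays differed widely: PFD0310w ran from -0.944 on array 1 to -0.083 on array 4, and PFL2405c from 1.665 on array 1 to -0.368 on array 3. PF13_0011 passed as lower when adjusted over the list alone, and over all genes without array 4 (-1.06, adjusted p = 0.0417). The 3 sporozoite or liver-stage genes, PF11_0224 at -0.004, PFB0915w at 0.26 and PFC0210c at 0.42 (n = 3), did not pass.

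**Figure D3:**
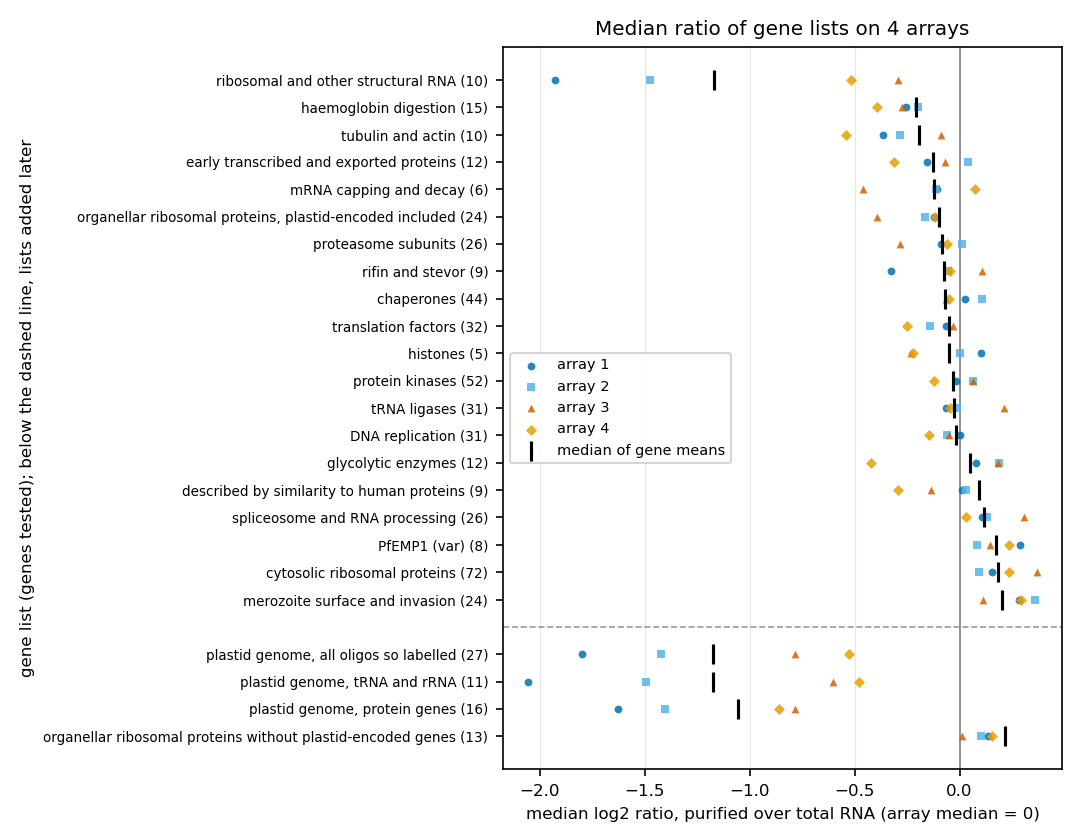
Median log2 ratio of purified over total RNA (horizontal axis) of each gene list with at least 5 genes tested (vertical axis, number of genes in brackets), with one point per array and a bar at the median of the gene means; lists under the dashed line were added after the data were seen. The structural RNA list and the 3 plastid lists lie between -1.17 and -1.06, and all other medians lie between -0.21 and 0.21.

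The arrays shared their pattern of ratios to very different degrees. Across genes, which are not independent replicates, Pearson's r was 0.715 between arrays 1 and 2 and 0.020 between arrays 3 and 4. The other pairs lay between 0.238 (arrays 1 and 3) and 0.357 (arrays 2 and 3). Spearman's rho was 0.659 between arrays 1 and 2. Different oligos of one gene, for 453 genes with several oligos on all 4 arrays, had an intraclass correlation of 0.365, with an SD of 0.27 between oligos of a gene against 0.339 over all such oligos.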

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

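The tests of explanations here were chosen after the results were seen. One result out of 51 sets of 4 array values was flagged, because one array lay far from the other 3; chance alone would flag about 2.6. The list of organellar ribosomal proteins had medians of -0.12, -0.16 and -0.12 on arrays 1, 2 and 4 and -0.39 on array 3, a gap of 0.836 of the whole range.

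Plastid oligos fell on both sides of 0 while most lay far below it. Random noise of single spots was argued against as the whole of what set the sign: of 32 plastid oligos measured on arrays 1 and 2, 6 of the 7 above 0 on array 1 were above 0 on array 2, and 24 of the 25 below 0 were below it again (Fisher's exact test, two-sided, p = 5.23e-05), although these arrays may share a purification, and of the 5 above 0 on array 1 and measured on array 3, 2 were above 0 there and all lay between -0.16 and 0.09 (p = 0.0476). A low reading of spots without specific signal could be checked only on control and empty spots with values on at least 2 arrays. These had medians of 0.387, 0.098 and 0.026 on arrays 1 to 3 against -1.716, -1.212 and -0.742 for plastid oligos (exact Mann-Whitney test, two-sided, p = 0.00337, 0.0204 and 0.00731). Single control spots reached -1.166 on array 2 and -1.191 on array 3, and array 4 had values for 2. Control spots without such readings were absent from the deposited values, and the test took spots as its units. The spots kept thus did not read low as a group, but a low reading of dim spots in general stays open. A dye effect on single oligos stays open, as no dye was swapped. The means of the tufA oligos, over 4 and 3 arrays, differed by 0.028, and those of the Clp spots, over 4 and 2 arrays, by 3.93. On single arrays the tufA oligos agreed less, at -1.612 and -1.034 on array 2 and -0.846 and -1.635 on array 3. The design has one group, so no biological explanation was tested.

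Arrays 3 and 4 correlated little, with an r of 0.020, although plastid genes had medians below 0 on both (-0.78 and -0.53). Feature rows took up 10.3% of the variance of array 3 and 6.2% of that of array 4. Removing block, row and column medians raised r to 0.132 (standard error 0.019, taking genes as independent). This was still below 0.28, the lowest r of the other pairs under the same adjustment. Block, row and column trends as removed here thus did not account for all of the difference, and other patterns on the slide were not tested. Whether the arrays that share a purification are the ones that correlate could not be tested, because no label ties arrays to purifications. No biological explanation was tested.

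Whether chance could give the 33 genes cannot be judged from splits of 4 arrays: turning the sign of whole arrays gives 8 distinct splits, too few for a share under 0.05. The data as measured gave the count of 33 in 1 of the 8, and the highest count among the others was 0.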

How the results depend on the processing

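The averages of arrays in pairs, the slide adjustment, the removal of the numbered oligos, the added lists and the correlations without organelle or called genes were chosen after the data were seen. The count of 33 genes stayed within 1.5 times of itself without further centring, with mean centring, imputed values, genes on all 4 arrays, single oligos, robust eBayes, the slide adjustment and without the numbered oligos. It was 15 with genes on at least 2 arrays (0 higher; 355 higher and 376 lower at an unadjusted p under 0.05 in limma), 65 at an adjusted p of 0.1, 3 when tested against a log2 ratio of 0.5, 370 in the authors' SAM calls (without the 1 control or empty spot among the 371 of the authors' deposited table) and 371 in the recomputed SAM. Leaving out one array gave from 0 (array 2) to 164 genes (array 3), with 33 and 26 of the 33 genes past the threshold without array 3 and without array 1; averaging arrays 1 and 2 and arrays 3 and 4 gave 0 genes (203 higher and 235 lower at an unadjusted p under 0.05), and the pairings of 1 with 3 and of 1 with 4 gave 494 and 4. None of the 33 changed sign in any of these limma fits, and the bait stayed below 0 and short of the threshold in all of them. For the 33, fits that left out or averaged arrays could not change the sign, since each had one sign on all arrays that measured it. The fry test asks whether the genes of a list on all 4 arrays moved one way on balance, not whether they differed from other genes. Adjusted p for cytosolic ribosomal proteins was 0.205 with an estimated correlation, 0.084 by fry (58 of 72 genes) and from 0.000423 to 0.0837 without one array. For structural RNA it was 0.403 with an estimated correlation, 0.141 by fry (4 of 10 genes), 0.0685 with the slide adjustment and from 0.000211 to 0.0719 without one array. For all plastid genes it was 0.0551 with an estimated correlation and 0.0157 by fry (14 of 27 genes). For plastid protein genes it was 0.0308 with an estimated correlation and 0.0157 by fry (11 of 16 genes). For plastid tRNA and rRNA it was 0.247 with an estimated correlation and 0.0246 by fry (3 of 11 genes). Correlations were estimated from these same few genes, at 0.936 for plastid tRNA and rRNA and 0.667 for structural RNA, so they are imprecise. Organellar ribosomal proteins and merozoite genes passed when arrays 1 and 3 and arrays 2 and 4 were averaged (0.0397 each), the former without plastid-encoded genes passed over genes on all 4 arrays (0.0494) and by fry (0.0205), and splicing genes ranged from 0.0337 to 0.418 without one array. Lists without a call whose direction in the camera test changed had adjusted p from 0.46 to 0.932 (tRNA ligases), 0.495 to 0.929 (glycolysis), 0.816 to 0.929 (DNA replication), 0.436 to 0.951 (capping and decay) and 0.736 to 0.951 (similarity to human proteins) without one array. Over genes on all 4 arrays they had 0.962 (glycolysis) and 0.94 (DNA replication and similarity to human proteins). Glycolysis had 0.784 with the slide adjustment and 0.956 without numbered oligos. PfEMP1 genes had 0.718 with imputed values and 0.721 with genes on at least 2 arrays, and the similarity list 0.718, 0.897 and, for single oligos, 0.818. Over all settings, medians ran from -0.21 to 0.04 for organellar ribosomal proteins, -0.13 to 0.02 for translation factors, -0.14 to 0.02 for tRNA ligases, -0.20 to -0.06 for the proteasome, -0.08 to 0.02 for chaperones, -0.11 to 0.03 for histones, -0.01 to 0.27 for glycolysis, -0.11 to 0.07 for DNA replication, -0.06 to 0.04 for kinases, -0.18 to -0.02 for capping and decay, -0.21 to -0.03 for early transcribed proteins, 0.05 to 0.29 for PfEMP1, -0.15 to -0.03 for rifin and stevor and -0.04 to 0.20 for the similarity list. The r of arrays 3 and 4 was -0.020 with imputed values, -0.010 without organelle genes and -0.036 without called genes. Without one array PF11_0224 ranged from -0.13 to 0.15 (0.021 with the slide adjustment), PF13_0258 from -0.15 to 0.12 and PFC0210c from -0.051 to 0.866. The cause of these changes was not tested; fits without one array have fewer degrees of freedom. Loess, filters on dim spots, background correction and the relation to abundance were not run, since they need channel intensities, and a fit with the purification as a block was not run, since no label gives it. No paired analysis was possible because the series has one group. What signal over background limits could not be assessed, beyond that genes on 3 arrays had a wider spread of means (SD 0.521) than genes on 4 (SD 0.373).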

Other observations

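The genes and groups in this part were chosen, and their tests designed, after the values were seen. Of the 17 lower genes not encoded in an organelle, 4 were described as transporters or ATPases. They were PFA0310c, a calcium-transporting ATPase, at -1.29 (adjusted p = 0.0259), PFE1150w, the multidrug resistance protein of the food vacuole membrane, at -1.22 (adjusted p = 0.0354, but 0.119 at -0.93 without a set of numbered oligos), MAL13P1.271, a putative vacuolar ATPase, at -1.21 (adjusted p = 0.0297), and PFE0410w, a putative triose or hexose phosphate translocator, at -1.06 (adjusted p = 0.0311). Each was lower on 4 of 4 arrays, as was every lower gene past the threshold with a value on all 4 arrays. Others of the 17 were MAL13P1.344, a putative RNase L inhibitor, at -1.31, PF14_0511, a bifunctional enzyme of the pentose phosphate pathway, at -1.20, and PFE0270c, a putative DNA repair protein, at -1.03. PFM0516, an unannotated feature of chromosome 13, and chr13.glimmerm_1053, a gene-finder prediction, were at -2.22 and -2.15 on the 3 arrays that measured them.

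All 37 genes described as transporters or ATPases had a median of -0.24 and a mean of -0.24, against a mean of 0.02 for other genes, and the 33 of them that had not passed the threshold singly had a median of -0.23 and a mean of -0.12. The group was drawn up because members were seen to be lower, so camera tests run on the same arrays are circular and were set aside, and some members, such as a cell division cycle ATPase, are not transporters. No technical explanation was tested for it.

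Gene-finder predictions without a locus name lay higher than other genes, with a mean of 0.25 over 136 genes against 0.01; they too were grouped after their values were seen, so the camera test of the group was set aside as well. One of them passed as higher, chr3.glimmerm_338 at 1.5 (n = 3, adjusted p = 0.0392), and one as lower, chr13.glimmerm_1053. Weak spots that read higher in Cy3 could account for this, as 44.1% of the predictions had a blank array against 21.1% of other genes. On 3 arrays the predictions had a mean of 0.41 against 0.09 for other genes, and on all 4 arrays 0.12 against -0.02, a difference of 0.141 against 0.243 over both. The difference was smaller where no value was blank but above its standard error across genes of 0.049, and the number of arrays is a coarse measure of signal, so this explanation stays open. No biological explanation was tested.

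A set of oligos with numbered names carried several oligos for a few genes; what the numbers stand for is not given in the sources used here. For PFE1150w the means were -0.94, -1.57 and -1.42 for the oligos numbered 100, 90 and 80. The oligos numbered 70, 60 and 50 in the same series had no gene identifier and were at -0.93, -0.51 and -0.29 (n = 3 for the last). Without the numbered oligos PFE1150w had a mean of -0.93 and did not pass (adjusted p = 0.119).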
